A study of Mus musculus with 8 samples.

How the data were processed

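Gene expression was measured in brown adipose tissue of 8 mice on Affymetrix Mouse Gene 1.1 ST arrays, which carry probes along the length of each transcript. The samples were 4 knockout mice that lacked the glucocorticoid receptor in brown fat (GRBATKO) and 4 control mice. Per the labels, all 8 mice were 16 to 20 weeks old when they were moved to 5 °C, where they stayed for 1 week. The sample labels call the controls wild type, and the series' design text calls them Flox, that is, mice with the receptor gene flanked by recombination sites. The extraction protocol in the labels names peritoneal macrophages as the source of RNA, which conflicts with the tissue field. Ucp1, the uncoupling protein of brown fat, ranked 1 or 2 among all probe sets on every array, so the values were read as those of brown adipose tissue. Array position codes in the sample descriptions put all 4 controls in rows A and B and all 4 knockout mice in rows C and D, so array row and genotype cannot be told apart, while both groups held columns 5 and 7.

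Values were summarised with RMA (robust multi-array average), per the submitters' processing notes, and the deposited table holds 1 linear-scale intensity per probe set and array. The RMA version, the genome build and any batch correction are not given in the sources used here. The scale was taken from the values themselves, which ran from 2.07 to 9168 with array medians between 21.4 and 21.7. RMA gives log2 values, so the intensities had been returned to a linear scale before deposit, and log2 was taken again before any test. No detection call or background level was used, so a low value has no known distance from background, and the number of arrays limits the precision.

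The table has 21115 probe sets numbered by gene. The platform annotation gave 1 gene symbol for 20405 of them and none for the other 710, which were tested but are unnamed here; no probe set had several symbols. Every one of the 20405 gene numbers was found in the RefSeq table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only, because the build behind the array values is not named. No column of the table belonged to an unlabelled sample.

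Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) over all 21115 probe sets with the genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fit had 6 residual degrees of freedom and a prior worth 3.46. For single genes and for the mean of a gene list per mouse, a two-sided exact permutation test of 4 against 4 values was run, in which 70 arrangements allow no p below 0.0286. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01 against all other named probe sets, adjusted over 35 lists. The lists held 712 entries, of which 650 were measured, and covered receptor targets, brown fat and lipid metabolism, stress and immune responses, and markers of other cell types a fat depot could hold. The receptor gene Nr3c1 itself was in no list.

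The groups, tests, lists, the rule for naming genes and all alternatives but 3 were chosen before the data were examined. The rule named 8 genes always (Nr3c1, Fkbp5, Tsc22d3, Per1, Ucp1, Ppargc1a, Dio2, Adipoq). It then named up to 8 genes per direction with adjusted p under 0.05 and groups that did not overlap, filled where short with the genes of smallest unadjusted p. Of each list it named members with adjusted p under 0.05 (at most 4), and otherwise the 2 members of smallest unadjusted p. Predicted genes and olfactory and vomeronasal receptors were left out of the second part. Named outside the rule, after their values were seen, were Dhcr7, Atp2a1, Ryr1, Ckmt2, Npas2, Arntl, Acta1, Ighm, Cd8b1, Thy1, Slc35g1, Hcar1, Gpat3, Cish, the neighbours of Ucp1 and 1 probe set without a name.

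Alternatives were a variance prior with an intensity trend, a robust prior, the ordinary t statistic, array weights, repeated quantile normalization, median centring, filters on dim probe sets (means below the 40th percentile) and flat ones (interquartile range up to 0.25), blocks for replicate number and array column, marker means as covariates, other thresholds, an estimated correlation in camera, the rotation test fry, and leaving out each array. The 3 added later left out pairs of arrays or list members. The pipeline was tested on simulated data for this comparison, with 200 of 21115 probe sets changed in each of 5 simulations. It recovered 59.2% of changes of 1.5-fold, 86.8% of 2-fold, 97.6% of 3-fold and 99.6% of 4-fold, and 5.30% of its calls were false. The simulated noise was normal and independent between probe sets, while real probe sets vary together. With 200 changed probe sets the adjusted threshold is also easier to reach than in the real data, where 5 passed. These shares may therefore not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.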

Results

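Brown adipose tissue, the fat depot that burns lipid to make heat, was profiled in 4 control and 4 GRBATKO mice after 1 week at 5 °C. The comparison asked how loss of the glucocorticoid receptor in brown fat changes gene expression in the cold; no mice kept warm were analysed here. Array medians lay between 4.42 and 4.44 on the log2 scale. Correlations between arrays over all probe sets were 0.990 to 0.993 within groups and 0.990 to 0.993 between groups. Control 1 and control 4 had a narrower spread of intensities, with 25th percentiles of 3.03 and 3.05 against 2.84 to 2.90 on the other arrays, and lay apart on the first principal component (23.7% of the variance). All control arrays lay in rows A and B and all knockout arrays in rows C and D, so every difference between genotypes below was also one between array rows. The labels number the mice but do not say how tissue was collected from each, so p-values measure the spread between these samples, which may be partly technical.

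Nr3c1 (probe set 14815_at), the glucocorticoid receptor gene that was targeted, fell in the knockout to 0.549 of the control level. Its log2 intensity was 8.61 ± 0.08 (SD, n = 4) in control and 7.74 ± 0.10 (SD, n = 4) in GRBATKO tissue, a log2 difference of -0.86 (SE 0.08, limma adjusted p = 0.00697), and every knockout mouse lay below every control mouse (two-sided exact permutation test, p = 0.0286). The 4 knockout values ran from 7.61 to 7.83 and the control values from 8.51 to 8.68, so the labels of all 8 arrays matched this gene. Where the probes of this set lie relative to the deleted part of the gene is not given in the sources used here. The 5 measured genes on either side of Nr3c1 differed by -0.18 to 0.28, none past the threshold.

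Besides Nr3c1, 4 genes changed. Elmod2, which codes for a protein that activates GTP hydrolysis by small Arf-family GTPases, rose 7.90-fold, from 7.37 ± 0.18 to 10.35 ± 0.14 (log2, SD, n = 4), a log2 difference of 2.98 (SE 0.11, limma adjusted p = 5.587e-06). Cyp2b10, a cytochrome P450 of xenobiotic metabolism, fell by 2.02 (SE 0.18, limma adjusted p = 0.00595), to 0.246 of control. Hsd11b1, the enzyme that regenerates active corticosterone from its inert 11-keto form, fell by 1.12 (SE 0.13, limma adjusted p = 0.0432), to 0.460 of control. Cdkn1a, the cell cycle inhibitor p21 and a known glucocorticoid target, fell by 0.97 (SE 0.08, limma adjusted p = 0.00595), to 0.509 of control. In each of these 4 genes the 4 knockout mice lay on one side of the 4 control mice, as the rule for naming them required.

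**Figure D1:**
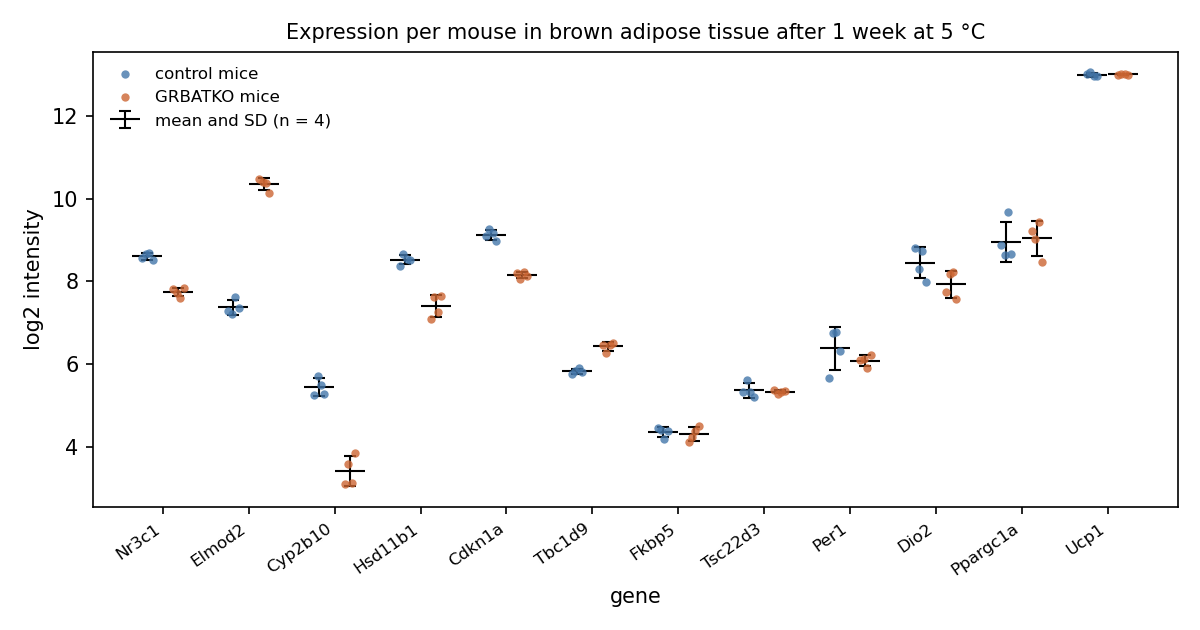
Log2 intensity (y axis) of 12 genes (x axis) in each of 4 control and 4 GRBATKO mice, with the mean and SD of each group (n = 4). Elmod2 averaged 10.35 in the knockout against 7.37 in control, Nr3c1, Cyp2b10, Hsd11b1 and Cdkn1a were lower with no overlap of mice, and Ucp1 lay at 13.02 against 13.01.

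These 5 genes, 1 higher and 4 lower, were all of the 21115 probe sets past the threshold in the limma fit. At an unadjusted p under 0.05 there were 1821 probe sets, 892 higher and 929 lower, where chance alone gives 1056. Much of that excess also arose without the genotype: the other 34 splits of the arrays into 4 and 4 gave up to 1700, with 959 to 1700 in the 14 that kept control 1 and control 4 together and 533 to 1145 in the 20 that parted them. Mice of the groups did not overlap in 1190 probe sets (5.64%), against 2.86% by chance. The size of the count depended on the variance model and the scaling: it was 30 with an intensity trend in the prior (18 higher, 12 lower), 1 with the ordinary t statistic (Elmod2), and 2 higher and 4 lower with arrays centred on their medians. Hsd11b1 was past the threshold in 8 of 22 alternative settings and Elmod2 in 22 of 22.

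The remaining genes of smallest p did not pass. On the higher side were Mogat1, an enzyme of diacylglycerol synthesis (log2 difference 0.58, SE 0.07, limma adjusted p = 0.0509), Tbc1d9 (0.60, SE 0.08, limma adjusted p = 0.0552), Lacc1 (0.62), Hace1 (0.54), Ndn (0.55), Plce1 (0.53) and Rassf2 (0.53). On the lower side were Prodh, which starts proline breakdown (-1.08, SE 0.15, limma adjusted p = 0.0810), Acss3, a mitochondrial acyl-CoA synthetase (-0.70), the acute phase gene Orm3 (-1.04) and Pdlim2 (-0.63). Each of these 11 genes had no overlap between the 4 control and 4 knockout mice, which largely follows from their choice by smallest p.

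Tbc1d9 and Elmod2 are the nearest measured genes on either side of Ucp1 on the chromosome. Ucp1 itself differed by 0.01 (SE 0.06, limma adjusted p = 0.968). The next measured genes outward, Rnf150 and Mgat4d, differed by 0.04 (SE 0.10) and 0.05 (SE 0.07). None of the other genes up to the fifth on either side passed the threshold.

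**Figure D2:**
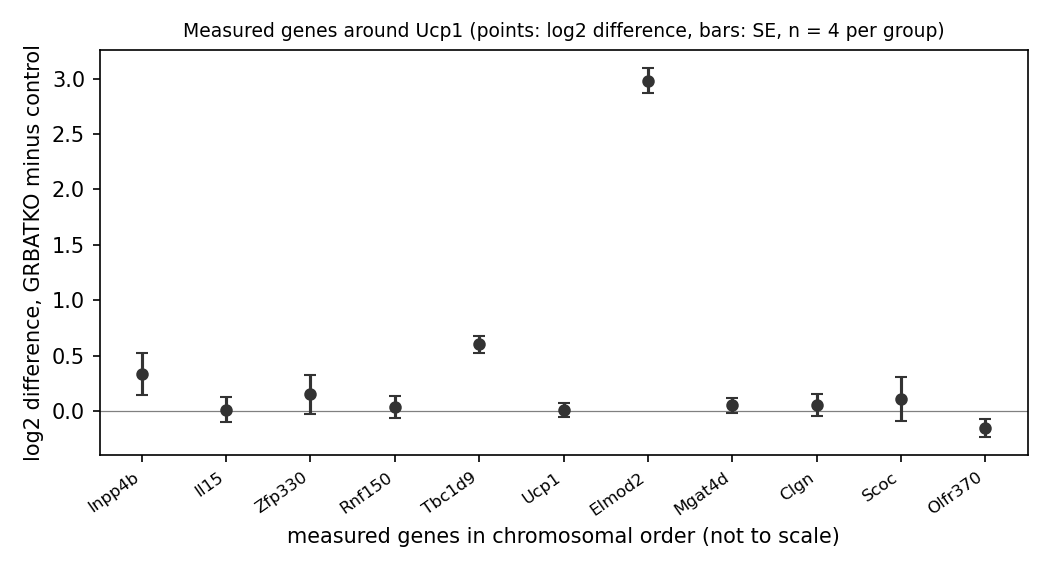
Log2 difference of GRBATKO minus control (y axis; points, with SE bars, n = 4 per group) for Ucp1 and the 5 nearest measured genes on each side, in chromosomal order and not to scale (x axis). Elmod2 stands at 2.98 and Tbc1d9 at 0.60, with Ucp1 between them at 0.01.

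Genes that glucocorticoid receptor is known to induce were lower as a group. Of 36 measured members 1 fell (Cdkn1a), none rose and 28 had a lower mean in the knockout, and the count adjusted over the list alone was also 1. The list mean was 0.06 ± 0.06 (SD, n = 4) in control and -0.06 ± 0.02 (SD, n = 4) in GRBATKO mice, with no overlap (two-sided exact permutation test, p = 0.0286, adjusted over the lists p = 0.333; limma camera adjusted p = 0.0223). Camera gave adjusted p = 0.286 with an estimated correlation, although the estimate of -0.0036 lay below the preset 0.01. It gave adjusted p = 0.118 without Cdkn1a, a member left out after its value was seen. Control 2 held the highest list mean, 0.14, and the list gave adjusted p = 0.163 without it, adjusted p = 0.0589 without control 3 and adjusted p = 0.0765 without control 3 and GRBATKO 4. The classical targets Fkbp5, the receptor's co-chaperone, Tsc22d3 (GILZ) and the clock gene Per1 differed by -0.04 (SE 0.10), -0.03 (SE 0.09) and -0.30 (SE 0.22), none past the threshold. Per1 was 5.66 in control 1 against 6.32 to 6.78 in the other controls, and differed by -0.54 without control 1 (adjusted p = 0.400) and by -0.16 without control 3. Of 10 measured genes of corticosteroid receptors and corticosteroid metabolism 1 fell, Hsd11b1 (1 also when adjusted over the list alone), and the list did not pass (limma camera adjusted p = 0.828).

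Genes of fatty acid and sterol synthesis were higher as groups. Of 21 measured genes of de novo lipogenesis 19 had a higher mean in the knockout, and the list mean was 0.12 higher with no overlap of mice (limma camera adjusted p = 0.00031). Camera gave adjusted p = 0.124 with an estimated correlation, although the estimate of 0.0050 lay below the preset 0.01. No member passed over all genes, while 2 did when adjusted over the list alone: Acss2, which makes acetyl-CoA from acetate (0.27, SE 0.07), and Insig1, a sterol-regulated brake on the same pathway (0.38, SE 0.10). For cholesterol synthesis and uptake the mean shift was 0.11, with 11 of 16 members higher (limma camera adjusted p = 0.00687; adjusted p = 0.893 with an estimated correlation). None of its members passed over all genes and 3 did when adjusted over the list alone, Mvd (0.37, SE 0.09), Insig1 and Dhcr7 (0.28, SE 0.08), the last named after its value was seen. Without GRBATKO 2, the mouse highest in lymphocyte markers, the cholesterol list gave adjusted p = 0.0655 and a shift of 0.07, and it gave adjusted p = 0.0521 after repeated quantile normalization and adjusted p = 0.101 without control 1 and control 4.

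Thermogenic genes of brown fat did not pass as a list of 29 (mean shift -0.12, limma camera adjusted p = 0.169), and no member passed over all genes. The list did pass, on the lower side, in 6 of 24 alternative settings: after repeated quantile normalization (adjusted p = 0.0493), with dim (adjusted p = 0.0163) or flat probe sets left out (adjusted p = 0.0464), and without control 1 (adjusted p = 0.0210), control 4 (adjusted p = 0.0496) or both (shift -0.21, adjusted p = 0.00145), the 2 arrays with the narrower spread. The adjusted p = 0.984 with an estimated correlation. Ppargc1a, the coactivator of mitochondrial biogenesis, differed by 0.07 (SE 0.26), and Dio2, which makes active thyroid hormone, by -0.53 (SE 0.21, limma adjusted p = 0.561). Ppargc1a was 9.68 in control 3 against 8.64 to 8.89 in the other controls, and differed by 0.31 without control 3 (adjusted p = 0.695), 0.50 without control 3 and GRBATKO 4 and -0.11 without control 1 and control 4. Adjusted over the list alone 2 members passed, Bmp8b, a secreted factor of heat production (-1.15, SE 0.25), and the creatine kinase Ckb (-0.71, SE 0.16). General adipocyte genes, 17 measured, had a mean shift of 0.15 with no overlap of mice (two-sided exact permutation test, p = 0.0286) and did not pass (limma camera adjusted p = 0.147); Adipoq, which codes for adiponectin, differed by 0.10 (SE 0.07), Lep by 0.98 (SE 0.41) and Irs1 by 0.35 (SE 0.14). Respiratory chain, tricarboxylic acid cycle, fatty acid oxidation, lipolysis and glycolysis lists shifted by 0.00, 0.00, -0.01, 0.02 and -0.01, with camera adjusted p from limma of 0.967, 0.944, 0.924, 0.828 and 0.828.

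Creatine and calcium futile cycle genes were lower as a list (13 measured, mean shift -0.27, limma camera adjusted p = 0.0196; adjusted p = 0.756 with an estimated correlation). No member passed over all genes; Ckb and Alpl (-0.55, SE 0.14), the phosphatase of creatine cycling, passed when adjusted over the list alone. Its members Atp2a1, Ryr1 and Ckmt2 are also abundant in skeletal muscle, and without them, a choice made after the data were seen, the list gave -0.18 with adjusted p = 0.0596. Control 3 held a list mean of 0.55; without it the shift was -0.13 (adjusted p = 0.210), and with the muscle marker mean as a covariate it was -0.13 (adjusted p = 0.162). The list also did not pass without control 2 (-0.32, adjusted p = 0.0531), GRBATKO 1 (-0.23, adjusted p = 0.0981) or GRBATKO 2 (-0.24, adjusted p = 0.0533), though its shift stayed near that with all mice. Skeletal muscle markers moved in the same direction (30 measured, 27 lower, mean shift -0.54, limma camera adjusted p = 0.0045; adjusted p = 0.984 with an estimated correlation). Their list means were 2.02 in control 3 and 0.80 in GRBATKO 4, against -0.64 to 0.02 in the other 6 mice (two-sided exact permutation test of 4 against 4, p = 0.457), and without control 3 the shift was 0.04. The oxygen store Mb, the 1 member past the threshold when adjusted over the list alone, differed by -1.44 (SE 0.32, limma adjusted p = 0.278), and Tnnc1 by -0.38 (SE 0.12).

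**Figure D3:**
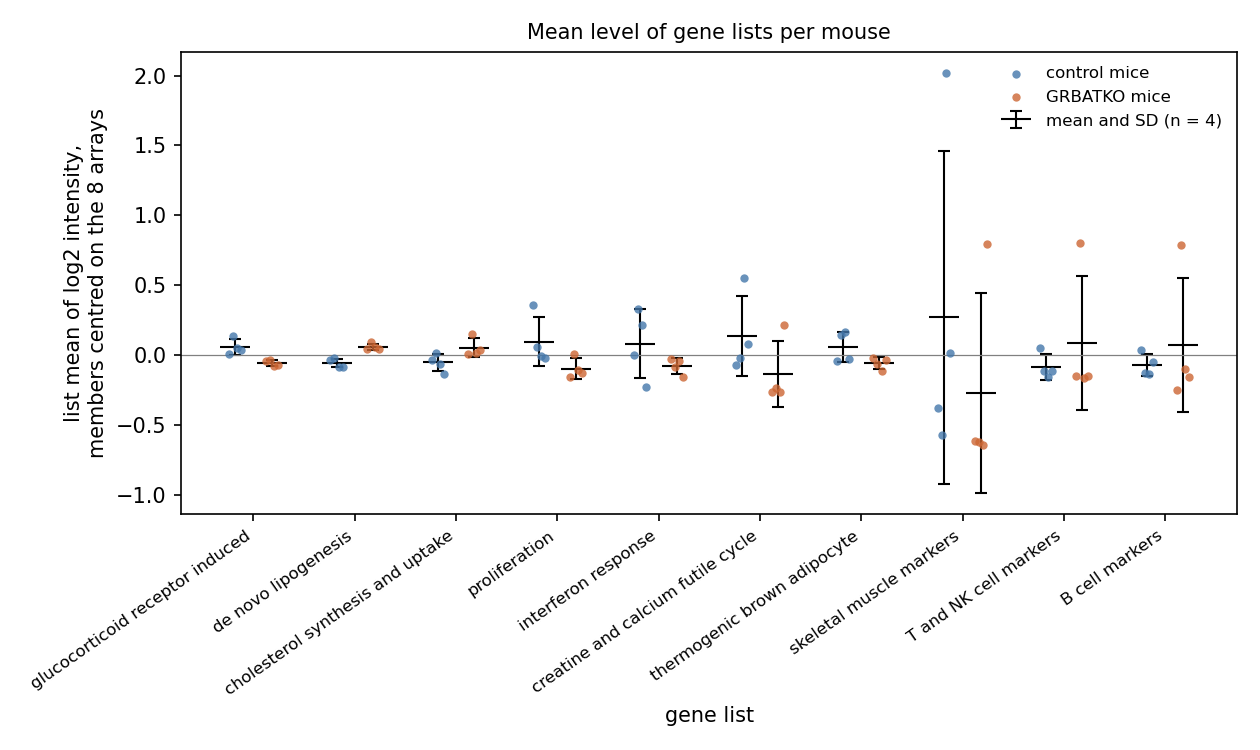
Mean log2 intensity of 10 gene lists (x axis) in each of 4 control and 4 GRBATKO mice, each member centred on its mean over the 8 arrays (y axis), with group mean and SD (n = 4). Receptor-induced and lipogenesis lists separate the groups without overlap, while muscle markers reach 2.02 in control 3 and T and NK cell markers 0.81 in GRBATKO 2.

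Proliferation genes were lower as a list (24 measured, 21 lower, mean shift -0.19, limma camera adjusted p = 0.00174; adjusted p = 0.893 with an estimated correlation). Its members of smallest p were Rrm2, a subunit of the enzyme that makes deoxynucleotides (-0.46, SE 0.18), and the mitotic motor Kif11 (-0.44, SE 0.17), and no member passed, over all genes or adjusted over the list alone. Control 1 held the highest list mean, 0.36, and without it the shift was -0.11 (adjusted p = 0.0730) and Kif11 differed by -0.28; Rrm2 differed by -0.30 without GRBATKO 1. Interferon response genes were lower too (24 measured, 20 lower, mean shift -0.16, limma camera adjusted p = 0.0114; adjusted p = 0.893 with an estimated correlation). Irf7, a transcription factor of the interferon response, differed by -0.47 (SE 0.10) and was the 1 member past the threshold when adjusted over the list alone. The interferon shift was -0.07 without control 2 (adjusted p = 0.372), -0.11 without control 3 (adjusted p = 0.191) and -0.09 without control 3 and GRBATKO 4 (adjusted p = 0.324). The interferon shift was larger without control 4 (-0.26, adjusted p = 4.977e-07), also the mouse lowest in macrophage markers, and without control 1 and control 4 (-0.35, adjusted p = 1.531e-09). Both p-values came from camera at the preset correlation of 0.01, while the estimate with all mice was 0.30, so they are likely too small.

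Of the 35 lists, 7 passed camera at the preset correlation, 2 higher and 5 lower, and none passed with an estimated correlation. The estimate was 0.0050 for de novo lipogenesis and -0.0036 for receptor-induced genes, and 0.074 to 0.638 in the other lists that had passed. In those 2 lists the estimate lay below the preset 0.01, so correlation between their genes was not what undid the call. Their unadjusted p in camera with the estimated correlation was 0.00353 and 0.0163. What else in that setting moved them was not tested. The rotation test fry, which tests whether a list's genes move on balance in one direction, called 2, de novo lipogenesis (adjusted p = 0.0157) and receptor-induced genes (adjusted p = 0.0466). Its mixed form, which counts changes in either direction, called 6. These were the same 2, cholesterol synthesis (adjusted p = 0.000126), inflammatory and acute phase (0.000126), corticosteroid metabolism (0.000295) and fatty acid oxidation genes (0.00126). The mixed form was not run on other splits of the arrays. Among all 35 splits of the 8 arrays into 4 and 4, 9 gave at least 7 lists by camera, the genotype split included, and 1 split, that by genotype, gave 5 genes.

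Lists that did not pass included inflammatory cytokines and acute phase genes (33 measured, limma camera adjusted p = 0.142), of which Orm1 (-0.42, SE 0.07) and Orm2 (-0.45, SE 0.08) passed when adjusted over the list alone. That list, with a mean shift of -0.04, did pass on the lower side in 4 of 24 alternative settings: with dim probe sets left out (adjusted p = 0.00584), with the muscle marker mean as a covariate (-0.08, adjusted p = 0.0251), without control 3 (-0.08, adjusted p = 0.0409) and without GRBATKO 2 (-0.08, adjusted p = 0.0457). Without control 1 and control 4 its shift was 0.02. Circadian clock genes shifted by 0.09 (limma camera adjusted p = 0.828), with Per3 at 0.84 (SE 0.26) and Tef at 0.45 (SE 0.17). Members went both ways, 10 higher and 8 lower, with Npas2 at -0.43 (SE 0.18) and Arntl at -0.34 (SE 0.17). A mean shift can miss such opposed differences, so this list test does not show that clock genes were unchanged. The clock list shifted by 0.20 without control 2 (adjusted p = 0.139), 0.02 without control 1 and -0.09 without control 1 and control 4 (adjusted p = 0.0911). Immediate early, oxidative stress, and unfolded protein and heat shock genes shifted by -0.09, -0.01 and -0.08, and Trib3, a stress-induced pseudokinase, by -0.53 (SE 0.15). Extracellular matrix, angiogenesis and secreted brown fat factor lists shifted by -0.02, 0.03 and 0.04, where Angpt1 differed by 0.57 (SE 0.16); the test direction and the mean had opposite signs for the matrix, fatty acid oxidation and nerve lists. Macrophage markers differed by -0.01 (28 measured, limma camera adjusted p = 0.898), and peritoneal macrophage markers by 0.11 (15 measured, adjusted p = 0.803, but adjusted p = 0.0404 with flat probe sets left out). Without GRBATKO 2 the peritoneal macrophage shift was 0.05 (adjusted p = 0.957). Macrophage markers rested on control 4, the lowest mouse at -0.37: without it they were lower in the knockout (-0.13, adjusted p = 0.00290), as they were without control 1 and control 4 (-0.11, adjusted p = 0.0330). Both p-values came from camera at the preset correlation of 0.01, while the estimate with all mice was 0.54. The groups overlapped in both settings, with GRBATKO 3 the highest of all mice at 0.25. Without control 1 and control 4 the glycolysis (-0.10), immediate early (-0.14) and unfolded protein and heat shock lists (-0.15) also passed, each at adjusted p = 0.0308. T and NK cell markers (shift 0.17) and B cell markers (shift 0.14) did not pass, and in both lists 1 knockout mouse, GRBATKO 2, stood apart at 0.81 and 0.79 against at most 0.05 in the others. Without GRBATKO 2 the shifts changed sign, to -0.07 and -0.10. T and NK cell markers passed without GRBATKO 3 (0.25, adjusted p = 0.0258) and with flat probe sets left out (adjusted p = 0.0464), and B cell markers without GRBATKO 3 (0.20, adjusted p = 0.0333), without GRBATKO 1 (0.25, adjusted p = 0.0278), without control 1 and control 4 (adjusted p = 0.0429) and after repeated quantile normalization (adjusted p = 0.0493). The estimated correlations with all mice were 0.53 and 0.44, far above the preset 0.01, and GRBATKO 2 was kept in each of these settings. Markers of granulocytes and mast cells, endothelium, fibroblasts, smooth muscle and pericytes, nerve, red cells and white adipocytes shifted by -0.04, 0.00, 0.00, -0.15, 0.01, -0.17 and 0.04. The smooth muscle and pericyte shift rested on control 4, at 0.50 against -0.13 to 0.03 in the other controls, and was -0.0072 without it. Red cell markers were lower without GRBATKO 4 (-0.27, adjusted p = 0.00257), without control 3 and GRBATKO 4 (-0.32, adjusted p = 0.00112) and with dim probe sets left out (-0.23, adjusted p = 0.0163), while without control 1 and control 4 they shifted by -0.04. The estimated correlation of the red cell markers with all mice was 0.42.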

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

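The tests of the genes beside Ucp1, the muscle markers, Mb and the lymphocyte markers were chosen after those results were seen; the counts over other splits of the samples were planned. Other splits of the 8 arrays into 4 and 4 were fitted in the same way, 35 in all. The split by genotype gave 5 genes past the threshold and no other gave more than 1, so 1 of 35 reached that count. That is the smallest share that 35 splits allow, so chance is an unlikely source of the count but is not excluded. The 5 genes include Nr3c1, the targeted gene, whose fall the design itself sets. They also include Elmod2, for which the Cre driver is a candidate explanation below. The splits were not counted without these genes. The count does not speak for any single gene. For gene lists the real count was 7, the highest of the other splits gave 12, and 9 of the 35 reached 7, so chance is not excluded as the source of the list calls.

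Elmod2 and Tbc1d9, the measured genes on both sides of Ucp1, were both higher in every knockout mouse. Genes with both neighbours higher at an unadjusted p of at most 0.001 numbered 2 among all measured genes, Ucp1 and Slc35g1. A candidate explanation is extra copies of the Ucp1 region carried with the Cre driver: such drivers for brown fat are often built from Ucp1 on a large piece of DNA that can hold neighbouring genes, although the labels do not name the driver used here. The other is a response of the region to loss of the receptor. A rise of Ucp1 was taken as its mark after the values were seen, though the neighbours could respond without Ucp1. Ucp1 differed by 0.012, at rank 1 or 2 of all probe sets where a rise may not be readable, so its value decides for neither explanation. Driver and receptor loss came in the same 4 mice, so the 2 explanations cannot be told apart with these arrays.

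Skeletal muscle markers averaged 0.797 in GRBATKO 4, far from the other 3 knockout mice at -0.642 to -0.617, and 2.02 in control 3, without which the groups differed by 0.04. Unequal carry-over of skeletal muscle with the fat depot is a candidate explanation that stays open: 96.4% of the variance of the 30 markers within groups lay on 1 component, but the high values of these 2 arrays had already been seen and fix that share, so it does not decide between carry-over and muscle-type expression in the fat itself. Acta1 was 9.29 in control 3 and 7.72 in GRBATKO 4 against at most 5.62 elsewhere. Mb went another way: with the mean of the other 29 markers as a covariate it still differed by -1.41 (SE 0.35). Carry-over that raises those markers together would thus not account for its lower level. That covariate rests largely on control 3 and GRBATKO 4, and Mb had the smallest p of the 30 markers. Carry-over that these markers do not follow and an effect of the genotype on Mb therefore both stay open. Of the 30 markers, 4 lay above the array median on every array, so that the tissue may express them itself, and 2 are also in the creatine and calcium futile cycle list.

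T and NK cell markers averaged 0.805 and B cell markers 0.786 in GRBATKO 2, against -0.164 to -0.148 and -0.251 to -0.0966 in the other 3 knockout mice. Lymphoid tissue in that sample is a candidate source that stays open: 80% of the 35 measured markers were highest in GRBATKO 2, which restates the list means that led to the test and would hold for an infiltration too; 4 of the 35 lay above the array median on every array, and 1 is in another list. Of these 4 abundant genes 3 were highest in this mouse, Ighm at 8.54 against 6.40 to 7.83 in the others, Cd37 at 6.64 against 4.95 to 5.39 and Cd8b1 at 6.18 against 4.49 to 4.93, while Thy1 was not, at 5.31 against 4.59 to 5.39. The other 3 knockout mice lay near the controls, so genotype alone does not account for the rise, and lymphoid tissue and infiltration in this mouse cannot be told apart.

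The remaining samples that stood far from the others of their group, with no explanation sought unless stated, were as follows. Ndn was 8.08 in GRBATKO 4 against 7.89 to 7.91. Bmp8b was 9.13 in control 4 against 9.52 to 9.53, and Cycs 6.63 in control 4 against 6.01 to 6.11. Mcpt4 was 3.21 in GRBATKO 4 against 3.74 to 3.83. Cspg4 was 6.87 in control 3 against 6.99 and above, and Hbb-bt 7.75 in control 1 against 7.31 to 7.33. The creatine and calcium futile cycle list, fitted above with the muscle marker mean as a covariate, averaged 0.217 in GRBATKO 4 against -0.265 to -0.235. Skeletal muscle markers were also high in that mouse, at 0.797. The angiogenesis list averaged -0.0615 in GRBATKO 3 against 0.0368 to 0.0395, the macrophage list -0.372 in control 4 against 0.0895 to 0.181, and the endothelial list 0.0576 in GRBATKO 1 against -0.0282 to -0.0158. The 75th percentile of the array was 6.67 in GRBATKO 3, below the other knockout arrays by under 0.01. Together with the muscle, T and NK cell and B cell lists described above, 14 were found in 246 groups tested, where chance gives 12.3.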

How the results depend on the processing

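Leaving out control 1 and 4, control 3 and GRBATKO 4, or list members was chosen after the data were seen; the other alternatives were planned. Nr3c1 was lower in all 22 settings, and its adjusted p passed the threshold in 17. It did not pass with the ordinary t statistic (-0.86, adjusted p = 0.0710), with a replicate block (-0.86, adjusted p = 0.157), without control 1 and 4 (-0.94, adjusted p = 0.0624), without control 3 and GRBATKO 4 (-0.87, adjusted p = 0.156) or without GRBATKO 2 (adjusted p = 0.0525); leaving out single arrays gave -0.90 to -0.82. The count of 5 genes became 30 with an intensity trend, 1 with the ordinary t statistic, 8 after repeated quantile normalization, 14 without dim and 10 without flat probe sets, both with fewer genes tested, 15 at an adjusted p under 0.1, 1821 at an unadjusted p under 0.05, 3 without control 1 and 4, and 2 without control 3 and GRBATKO 4, with fewer samples in both. It was 3 to 5 without single arrays, 3 without GRBATKO 2. The values gave no sign that replicate numbers pair the mice. Same-numbered mice deviated from their group means with correlations of -0.06 to 0.09, and 1 of 4 pairs matched best with its own number. The labels do not say what the numbers mark, and 4 pairs cannot exclude a pairing. A replicate block left 1 gene, Elmod2, and 6 lists, without that of receptor-induced genes (adjusted p = 0.0528). The 7 lists became 0 with an estimated correlation, 2 with fry and 12 without control 1 and 4, and 4 to 9 without single arrays, 4 without control 2 or control 3. Skeletal muscle markers changed sign without control 3 (0.0404); single arrays left out gave -0.90 to 0.0404. Leaving out 1 array moved the difference of 25 of 85 genes and the shift of 15 of 35 lists by over 1.5 times or to the other sign, where that was by over 0.05. With flat probe sets left out, and so fewer members, shifts were larger in several lists, as in general adipocyte genes at 0.46 (adjusted p = 0.101). Muscle and macrophage lists have no value with their own mean as a covariate. Elmod2 passed in 22 of 22 settings, Cdkn1a and Cyp2b10 in 19, and Hsd11b1 in 8. Of single genes and lists, 2564 values stayed on their side of the threshold (86 values that passed in neither setting changed sign), 51 no longer passed, 52 newly passed and 1 that had passed changed sign. Unless stated, the cause was not tested. No signal over background was used, so changes in dim genes may be missed.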

Other observations

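Hcar1, Gpat3, Cish and the unnamed probe set were chosen after their values were seen, and the other genes of this part by the naming rule; none passed the threshold in limma's planned fit. The 3 orosomucoid genes, acute phase proteins known to respond to glucocorticoids, were all lower in the knockout with no overlap between mice: Orm1 by -0.42 (SE 0.07), Orm2 by -0.45 (SE 0.08) and Orm3 by -1.04 (SE 0.16), with limma adjusted p of 0.154, 0.168 and 0.136. The 3 genes are near-identical copies, so their probe sets are uncertain as separate measurements. Over the alternative settings Orm3 lay between -1.25 and -0.89 and passed the threshold in 2 of 22. Hcar1, the lactate receptor that restrains lipolysis in adipocytes, differed by 1.04 (SE 0.17, limma adjusted p = 0.150), and Gpat3, an enzyme of triglyceride synthesis, by 0.55 (SE 0.09, limma adjusted p = 0.143).

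A probe set unnamed here, 66355_at, differed by -1.25 (SE 0.17, limma adjusted p = 0.0790). Among receptor targets, Cish, a brake on cytokine signalling, differed by 1.04 against the direction of its list, with an SE of 0.63. Xist was 2.40 in control and 2.32 in GRBATKO tissue and the Y-linked gene Kdm5d 5.96 and 6.11, with no difference past the threshold between groups in the sex chromosome list (limma camera adjusted p = 0.924). That list mixes Xist with Y-linked genes, which a sex difference would move in opposite directions, so its test is a weak check. Over all arrays Xist lay at 2.23 to 2.54, below the 25th percentiles of 2.84 to 3.05. Kdm5d lay at 5.81 to 6.31, above the array medians of 4.42 to 4.44. No array stood apart in these genes, and all 8 had the levels of male tissue, which argues against a sex difference between the groups.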
